A study of Mus musculus with 2 samples.

How the data were processed

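The series holds 2 samples of mouse lung RNA, 1 per genotype, each a mixture of RNA from 3 mice. Per the labels' protocols, total RNA was treated with DNase, checked on a Bioanalyzer and transcribed into digoxigenin-labelled cRNA with the Applied Biosystems chemiluminescent labelling kit. The array software, its background handling and the meaning of its codes are not given in the sources used here.

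Per the file headers, the deposited scanner tables give for each probe an intensity (a linear 1-colour signal), a signal-to-noise score and a software code, which is a whole number of the "other" kind and not a measurement. The intensity is positive for each of the 33012 gene probes (lowest 31.4), while probes that were not detected had medians of 290 in wild type and 249 in the Foxf1+/- array. An offset may therefore remain, which would pull ratios of dim genes toward 0. This was not tested. The 2 deposited scanner tables are identical, and each holds both arrays under codes that name no sample. The arrays were assigned through the authors' value table, whose columns are named by sample. Over all 33012 gene probes the intensity of 1 array was the authors' wild-type value times a constant (median ratio 755, largest deviation 1.05e-06%), and that of the other array the authors' Foxf1+/- value times another (842, 1.03e-06%), while the crossed pairs deviated by up to 106055% and 139664%. The authors' table is thus the deposited intensity divided by 1 constant per array, with column medians of 1.11 and 0.81. Its direction and scale are known relative to the scanner table, but the basis of the constants and of any centring is not. The mapping rests on this identity and not on any gene's level.

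From the intensity on, 303 control rows were left out, and so were probes with a software code above 5000 in either array (96 in wild type, 144 in the Foxf1+/- array), which left 32775. Spots with code 4 (44 in wild type and 23 in the Foxf1+/- array, none under a signal of 939912) were kept and are called out where named. Signals were log2 transformed and quantile normalized between the arrays. No background correction was added, since the files hold no separate foreground and background columns among those used here. A probe was called detected at a signal-to-noise of at least 3. A gene detected in 1 array only was given a bound, the bright array's value over the higher of the dim probe's own value and the lowest detected signal of the dim array, on the normalized scale, and is written "at least N-fold". Without scaling these bounds are lower for the named genes detected in the Foxf1+/- array only and higher for those detected in wild type only, apart from Slc18a2.

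Probes were named through the Entrez gene number in the file where the RefSeq gene table of the GRCm38.p6 assembly holds it (16500 probes), then through a RefSeq accession (349), else by the file's own symbol (317). No gene was named for 391 probes with several genes and 15455 with none, which stay as unnamed transcripts in the counts. The table was used for names and for which genes neighbour Foxf1, and no coordinates are given, since the sources used here name no genome build. A gene with several probes takes the probe of highest mean signal. Of the 3823 genes or transcripts detected in 1 array only, 7 had another probe detected in both, and 2 of these count as 2-fold apart.

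With 1 array per genotype no test between genotypes was made and no p-value is given. Genes were counted at a log2 ratio of at least 1 in either direction. The median log2 ratio of each of 33 gene lists (cell types, responses, other tissues) was set against 10000 random lists of the same size matched on mean signal in 20 bins, and a list stood apart if it lay in the outer 2.5% on either side with at least 5 members detected in both. The lists, the size rules and the rule for naming genes were set before the data were examined. The naming rule takes Foxf1, the 12 largest ratios in each direction among named genes with a signal-to-noise of at least 3 in both arrays and 10 in the brighter, the 4 largest bounds in each direction at a signal-to-noise of at least 10, per list up to 4 members at least 2-fold apart in each direction and its 3 brightest, and the members of any count of 5 or fewer. Foxf2, Prtn3, Csf3r, Hdc, Slc18a2, Hpgds, Tpsb2, Mcpt4, Mcpt1 and the genes named in the closing section were named in addition, after their values were seen.

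The calculation was tested on simulated arrays made from the measured mean signals with the probe-to-probe spread. Of 50 genes raised by a log2 of 1.5 and 50 lowered by as much, 90% of each were found at 2-fold or more, and 100% of those moved by 2.5. Of 200 unchanged lists 4% stood apart, and 49 of 50 lists shifted by 0.5 did. The unchanged lists were drawn from the same genes as the random lists, so a share near the limits set follows from the design. The lists held 15 genes that varied independently with 1 spread. Shifts of smaller lists, or of genes with a wider spread, may be found less often. The alternatives were median scaling, cyclic loess, no scaling, the authors' value table, a signal-to-noise of 10 in both, no detection filter, an offset of 50, coded spots kept, the mean of a gene's probes, other fold thresholds, other treatments of the random lists and, added after the data were seen, leaving out spots with code 64 or 65. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and limma 3.58.1 in R 4.3.3 for cyclic loess.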

Results

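Lung RNA was compared between male mice carrying 1 disrupted copy of Foxf1, a forkhead transcription factor of the lung mesenchyme and endothelium, and their wild-type littermates. Both groups were on the outbred Black Swiss background and had received a single intraperitoneal dose of carbon tetrachloride (CCl4, 0.5 microliter per g of body weight in mineral oil), a solvent that injures liver and lung. The lungs were taken 16 hours later. Equal amounts of RNA from 3 mice of a genotype were mixed, and each mixture was hybridised to 1 Applied Biosystems chemiluminescent 1-colour array, so the series held 2 arrays, 1 per genotype. The series title names lung inflammation and mast cell accumulation as its subject, and the comparison asks how the lung transcriptome after this injury differed with the loss of 1 Foxf1 allele. No uninjured lungs were analysed here, so a difference between the pools cannot be assigned to the response to CCl4 or to the genotype before it.

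The arrays carried 33012 gene probes. Of the 32775 probes used, 16862 (51.4%) were detected in the wild-type pool and 16848 (51.4%) in the Foxf1+/- pool at a signal-to-noise of at least 3. The median signal of detected probes was 6562 in the wild-type and 5251 in the Foxf1+/- pool before scaling. With 1 pooled array per genotype the differences have no replicate check, no test between genotypes could be made, and the number of arrays limits the precision. The only spread in hand was that between different probes of a gene. Over the 633 genes with at least 2 detected probes, the log2 ratio of a single probe had a technical SD of 0.39, and of 0.26 in the 255 genes whose probes were both above the median signal. This spread leaves out the variation between mice. Where the brightest probe of a gene gave at least a 2-fold difference and a second probe was detected (27 genes), the second probe had the same sign in 23 and was also at least 2-fold apart in 9. Ratios are given as Foxf1+/- over wild type on the quantile-normalized log2 scale, which sets the median gene to 0. Before scaling the median gene lay at -0.36, and in the authors' value table at -0.52. Bounds of genes detected in 1 pool are on the normalized scale too, and for those detected in the Foxf1+/- pool only the lower bound without scaling is given beside it.

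Foxf1 itself was measured by 1 probe, listed under the older symbol Foxf1a. Its signal was 139297 in the wild-type pool (signal-to-noise 66.1) and 50943 in the Foxf1+/- pool (signal-to-noise 59.3). The log2 ratio was -1.05, or 2.07-fold lower in the library labelled heterozygous, which is further from 0 than the probe-to-probe SD of 0.39. Without scaling it was -1.45, and in the authors' value table -1.61. The position of the probe relative to the inserted beta-galactosidase sequence is not given in the sources used here, so whether the disrupted allele was read by it is unknown. Foxf2, the closest relative of Foxf1, had a log2 ratio of 0.71.

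Of 17950 genes or unnamed transcripts detected in at least 1 pool, 1689 were at least 2-fold higher in the Foxf1+/- pool and 1339 at least 2-fold lower. The higher set held 617 detected in both pools and 1072 detected in the Foxf1+/- pool only, and the lower set 402 detected in both and 937 in the wild-type pool only. The 1019 detected in both were 7.21% of the 14127 measured there. In simulated arrays with the probe-to-probe spread and no change, 1.08% of 13926 genes passed 2-fold. The simulation gave all genes the same spread, although dim genes scattered more, and left out variation between mice. Its share is therefore no error rate for the 7.21%. Genes higher in the Foxf1+/- pool made up 55.8% of all calls of at least 2-fold. This split depends on the scaling. Without scaling 1104 were higher and 2426 lower (31.3% higher), and in the values tabulated by the authors 904 were higher and 3368 lower (21.2% higher).

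The genes furthest below wild type in the Foxf1+/- pool included products of neutrophils and of airway neuroendocrine cells. Ngp, a neutrophil granule protein, had a log2 ratio of -3.56 (11.8-fold lower), Il1r2, the decoy receptor of interleukin 1, one of -3.53, and Camp, the cathelicidin antimicrobial peptide, one of -2.53. Grp, the neuropeptide gastrin-releasing peptide, was 11.6-fold lower at -3.54. Ms4a8a was at -3.22, the serotonin receptor gene Htr2b at -2.61, Sos1 at -2.49, and Nfe2l2, which encodes the oxidative stress regulator Nrf2, at -2.44. The remaining genes of the 12 largest lower ratios were 2410116I05Rik (-2.32), Plcb3 (-2.31), the cardiac gene Lrrc10 (-2.22) and Plat, tissue plasminogen activator (-2.16 at a signal of 282240 in wild type). Detected in the wild-type pool only were Ppp1r17 (at least 20.7-fold lower in the Foxf1+/- pool), Tat, tyrosine aminotransferase (at least 12.3-fold), Bcar3 (at least 7.44-fold) and the fibrinogen gene Fgg (at least 7.31-fold).

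In the other direction, Sema3c, a secreted guidance ligand, was 8.49-fold higher in the Foxf1+/- pool (log2 ratio 3.09). The chemokine Cxcl12 stood at 2.74, and its second probe at 0.90. Cyp1a1, a xenobiotic-metabolising cytochrome P450, was 5.97-fold higher (2.58). Cspp1 (2.36), 2210407C18Rik (2.35), Lrat, which esterifies retinol (2.32), Nr1h4, the bile acid receptor FXR (2.30), Arsj (2.23), 4833432P19Rik (2.19) and Plk5 (2.10) followed. Hhip, the hedgehog-binding inhibitor of that pathway, was at 2.05 with a second probe at 0.74. Cflar, an inhibitor of caspase 8, was at 2.80 by a spot with a software code, while its other probe gave -0.49. Tff1, a trefoil peptide of gastric surface mucus, was detected in the Foxf1+/- pool only and at least 183-fold higher on the normalized scale, with a signal of 85751 against 592 (145-fold without scaling). H2-Ea, an MHC class II alpha chain, was at least 60.2-fold higher (51.5-fold without scaling), Gkn2, a gastrokine of the stomach surface, at least 32.2-fold (26.0-fold), and Fam122b at least 23.1-fold (19.7-fold). Of these 32 genes named by size, 7 had spots with software code 64 (Cflar, Plk5, Sos1, 2410116I05Rik, Fam122b, Ppp1r17 and Tat), against 2.46% of all detected genes. The dim spots of H2-Ea and Fam122b in the wild-type pool and of Ppp1r17 in the Foxf1+/- pool carried code 1.

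**Figure D1:**
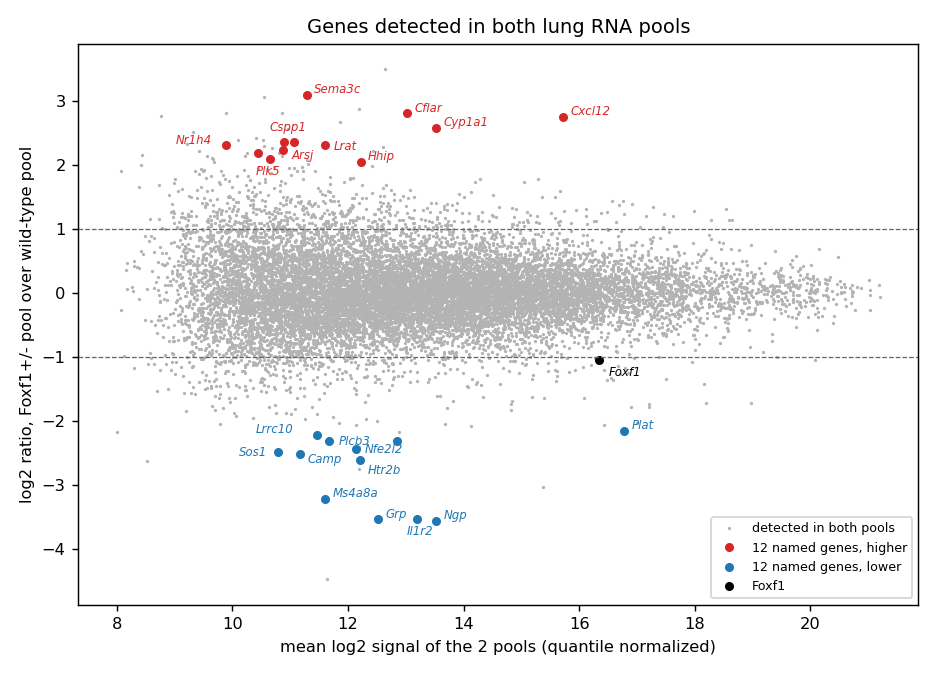
Log2 ratio of the Foxf1+/- pool over the wild-type pool (vertical axis) against the mean log2 signal of both pools (horizontal axis), quantile normalized, for the 14127 genes or unnamed transcripts detected in both (grey points, 1 array per pool, no error bars). Coloured points are the 12 named genes of each direction and black is Foxf1 at -1.05; dashed lines mark 2-fold. Ratios scatter more at low signal (SD 0.75 in the dimmest 10%) than at high signal (SD 0.38 in the brightest), and grey points beyond the coloured ones have no symbol or a signal-to-noise under 10 in both pools.

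Of the 33 gene lists fixed beforehand, 29 had at least 5 members detected in both pools. The medians of 9 lay in the outer 2.5% on either side of 10000 random lists of like size and signal. Chance would place 1.45 there if the members of a list varied independently. Members of real lists can vary together, which would place more there between any 2 pools. The percentile of a list describes these 2 libraries and is not a test between genotypes. List medians are relative to the median gene, and without that centring they lie lower by about its shift. The neutrophil list was lowest. Its 18 measured members had a median log2 ratio of -0.999 (percentile 0), with 9 at least 2-fold lower, 9 in between and 0 at least 2-fold higher. Ngp, Il1r2, Camp and Mmp8, the neutrophil collagenase (-2.06), led it. Of its brightest members, Retnlg was at -0.998, S100a8 at -0.84 and S100a9 at -0.36, the last by a spot of the wild-type array with code 4, borne by spots at the top of the signal range, so its difference may be understated. Prtn3 (0.31) and Csf3r (0.53), the receptor of granulocyte colony-stimulating factor, lay above 0.

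The acute phase and NF-kappaB list, which holds genes induced by cytokines in inflammation, had a median of -0.54 over 20 members (percentile 0). 19 members lay below 0 and 5 were at least 2-fold lower. These were the metallothioneins Mt2 (-2.04) and Mt1 (-1.04, second probe -1.18), Socs3, a feedback inhibitor of cytokine signalling (-1.43), the serum amyloid Saa3 (-1.37, second probe -1.66) and Serpina3n (-1.08). Lcn2, lipocalin 2, was at -0.93 and Nfkbia at -0.31. All 11 measured glucocorticoid-responsive genes were lower in the Foxf1+/- pool, with a median of -0.94 (percentile 0). Ddit4 (-2.05), Mt2, the cell cycle inhibitor Cdkn1a (-1.79), Fkbp5, a chaperone of the glucocorticoid receptor (-1.69), and Angptl4 (-1.21) were at least 2-fold lower. Mt2 and Lcn2 stand in both lists. The 7 glucocorticoid-responsive genes that stand in no other list had a median of -0.94. Of 13 measured core clock genes 10 were within 2-fold, and the list median was 0.06 (percentile 67.4), with Dbp at 1.02, Arntl, which encodes BMAL1, at -1.22 and Nfil3 at -1.25.

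Transcripts of heart and skeletal muscle, listed beforehand as markers of other tissue, were lower in the Foxf1+/- pool. Their median was -0.48 over 17 members (percentile 0). Whether they came from outside the lung was not tested. Myl3 (-1.61), Pln, phospholamban (-1.41), and Tnnt3 (-1.04) were at least 2-fold lower. The brightest, the cardiac myosin gene Myh6, had signals of 537888 and 283742 and a ratio of -0.48. Hepatocyte genes gave a median of -0.39 over 5 members (percentile 8.38), and a further 6 were detected in the wild-type pool only, 4 of them with a bound of at least 2-fold (Fgg, Fgb, Apoh and Apoa1). The adipose list had a median of -0.27 (percentile 14.955). The reference gene list, 12 genes often used to standardise expression, had a median of -0.22 (percentile 1.58), with none 2-fold apart. It stood apart from random lists under quantile but not under median or cyclic loess scaling.

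Interferon-stimulated genes were higher in the Foxf1+/- pool relative to the median gene. The median of 18 members was 0.61 (percentile 100), and 16 lay above 0. Without scaling the median was 0.27, and it was 0.11 in the authors' value table, above the median gene in each. Oasl2 (1.54), the GTPase Gbp3 (1.496) and Ifit1 (1.04) were at least 2-fold higher, Oasl1 was lower at -1.40, and Ifi44 was detected in the Foxf1+/- pool only (at least 3.52-fold higher, and 2.97-fold without scaling). Among the brightest members, Irf1 was at 0.19, Psmb9, an immunoproteasome subunit, at 0.95 and Psmb8 at 0.08. The fibroblast and extracellular matrix list had a median of 0.34 over 29 members (percentile 100), with 19 above 0, and lay at -0.06 without scaling and -0.21 in the authors' value table, above the median gene in each. Vim (0.51), Dcn (0.39) and Col3a1 (0.68) were its brightest members, and Eln, elastin, was its 1 gene at least 2-fold lower (-1.47). The list of mesenchymal signalling genes linked to Foxf1 had a median of 0.29 over 15 members (percentile 97.8), which is -0.05 without scaling and -0.21 in the authors' value table. It no longer stood apart at a signal-to-noise of at least 10 (percentile 97.01) or against random lists not matched on signal (97.37). Hhip and Wnt2 (1.12) were at least 2-fold higher, and Igfbp6 (-0.28), Hoxa5 (-0.09) and Tbx3 (0.12) were its brightest members.

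Mast cell genes, the cell type named in the series title, went both ways. The list had a median of -0.38 over 8 members (percentile 1.73), and of -0.24 over 7 (percentile 10.75) without Hdc, histidine decarboxylase (-0.52), which also stands in the neutrophil list. Serglycin (Srgn), which other leukocytes also express, was at -0.80, Gata2 at -0.24 and Kit at -0.03. The mast cell protease genes were unequal in direction. Tpsb2, the brightest of those measured, was at 0.23, Mcpt4 at -0.99 (signal-to-noise 14.4 and 5.49) and Mcpt1 at -0.73 (3.45 and 4). Cma1, mast cell chymase, was 2.59-fold higher (log2 ratio 1.375) at signals close to the detection limit (559 and 1183, signal-to-noise 3.11 and 4.58). Its second probe was detected in the Foxf1+/- pool only, with a log2 value of 1.364 (signals 543 and 1139, signal-to-noise 2.1 and 8.05). Tpsab1 and Cpa3, a tryptase and a carboxypeptidase of mast cells, were detected in the Foxf1+/- pool only, at least 7.42-fold and 5.43-fold higher (6.04-fold and 4.68-fold without scaling) with a signal-to-noise of 5.72 and 3.96. Slc18a2 and Hpgds were detected in the wild-type pool only, close to the detection limit, the latter at least 1.33-fold lower in the Foxf1+/- pool and the former with no fold. Counting members detected in 1 pool, the list median was -0.14 (percentile 18.0), with a signal-to-noise of at least 10 it was -0.24 (percentile 9.06), and with no detection filter -0.019 (percentile 45.4), so the list no longer stood apart.

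Other leukocyte lists did not stand apart. Macrophage and monocyte genes had a median of -0.09 over 19 members (percentile 17.035), among them Cd14, the co-receptor for lipopolysaccharide (-1.22), and the bright Lyz1 (-0.09) and Arg1 (0.04). Lyz2 (-0.05) carried code 4 in wild type, so its difference may be understated. T cell genes had a median of 0.26 over 7 members, MHC class II and co-stimulation genes one of 0.02 over 9, and B and plasma cell genes one of 0.44 over 6 (percentile 96.0), with Ms4a1, which encodes CD20, at 2.04 and Jchain at 1.03. NK cell genes (median 0.56) had 4 measured members and eosinophil and basophil genes (0.29) had 3, under the minimum of 5. Chemokines had a median of 0.07 over 22 members. Cxcl12 was higher, while the macrophage and neutrophil chemokines Ccl4 (-1.81), Cxcl2 (-1.78) and Ccl9 (-1.43) were lower. Cytokines had a median of 0.22 over 11, with Tgfb2 at 1.04. Red cell and platelet genes had a median of 0.20 over 8 (percentile 86.4).

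**Figure D2:**
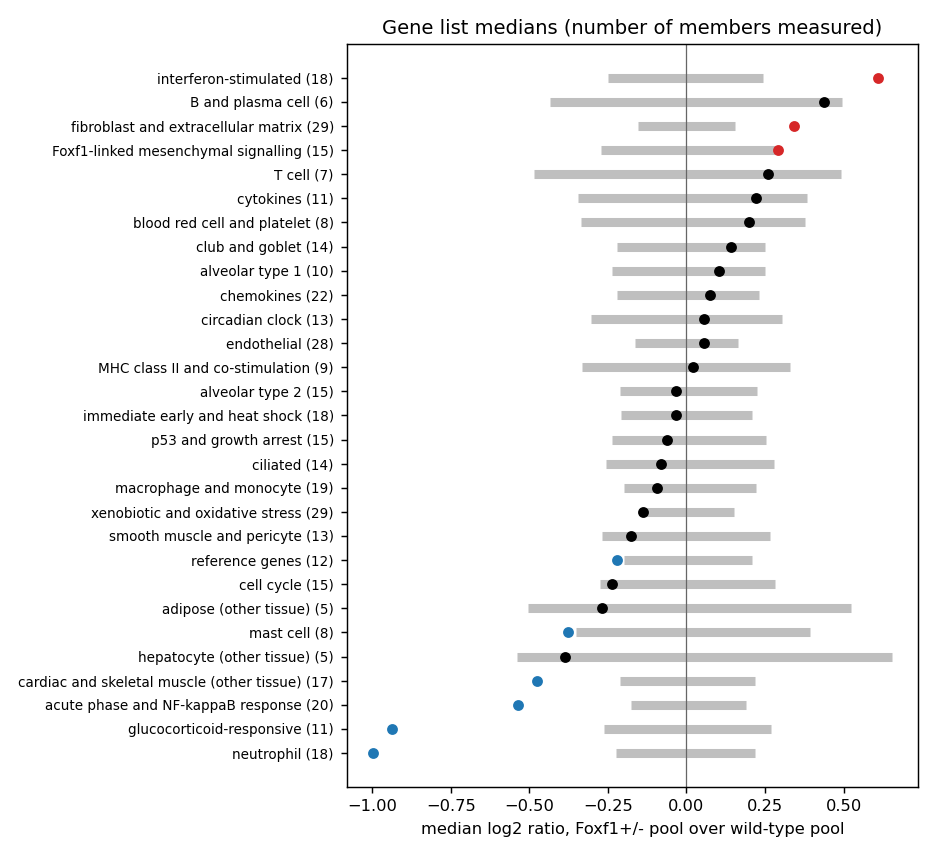
Median log2 ratio of the Foxf1+/- pool over the wild-type pool for the 29 gene lists with at least 5 members detected in both pools (number of members in brackets). Grey bars span the central 95% of 10000 random lists matched on size and signal; blue and red points are the 6 lower and 3 higher lists that lie outside it, from neutrophil genes at -0.999 to interferon-stimulated genes at 0.61, and black points lie within it.

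The other lists of resident lung cells lay within the range of random lists. The median of 28 endothelial genes was 0.05 (percentile 74.4), but its members were spread widely. Lyve1, a hyaluronan receptor of lymphatic and some other endothelium, was 3.30-fold lower (-1.72). Calcrl, the adrenomedullin receptor (1.90), Emcn, endomucin (1.72), and Kdr, the VEGF receptor 2 gene (1.03), were at least 2-fold higher, and the bright Cldn5 (-0.57) and Ramp2 (-0.58) lay below 0. Smooth muscle and pericyte genes had a median of -0.18 over 13 members, alveolar type 2 genes one of -0.03 over 15, alveolar type 1 genes one of 0.10 over 10, club and goblet cell genes one of 0.14 over 14 and ciliated cell genes one of -0.08 over 14. Sftpb (-0.04) and Scgb1a1 (-0.07), the brightest surfactant and club cell genes, carried code 4 in both pools, so no difference could be read from them.

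The remaining response lists were likewise within the range. Cell cycle genes had a median of -0.24 over 15 members (percentile 4.69), with 0 at least 2-fold apart in both pools and Mcm2 (at least 8.09-fold) and Top2a (at least 3.13-fold) detected in wild type only. Xenobiotic and oxidative stress genes had a median of -0.14 over 29 members (percentile 2.88). Cyp1a1 and Fmo2 (1.39) were higher, and Txnrd1, thioredoxin reductase (-1.40), and Por, the electron donor of microsomal P450 enzymes (-1.22), were lower. The p53 list had a median of -0.06 over 15, with Cdkn1a and Gadd45g (-1.13) lower. Immediate early and heat shock genes had a median of -0.03 over 18. The Y-linked Ddx3y, Eif2s3y and Uty were detected in both pools (median 0.47 over 3 members), and the thymocyte list had 1 measured member, Cd1d1 (0.68).

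**Figure D3:**
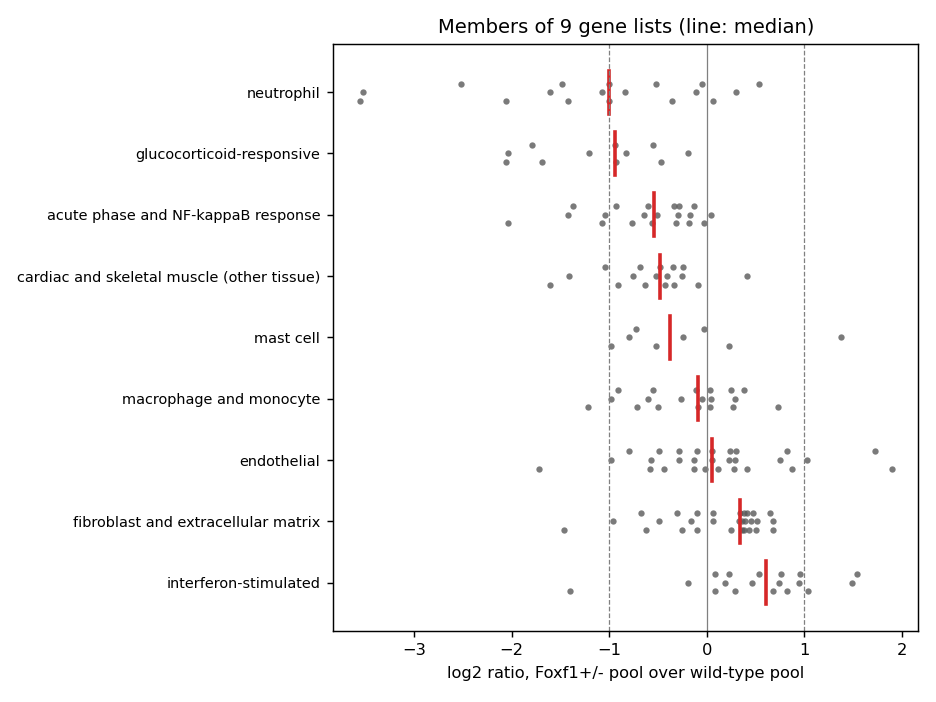
Log2 ratio of the Foxf1+/- pool over the wild-type pool for each member detected in both pools of 9 gene lists (grey points, 1 array per pool, spread vertically for legibility); red lines are list medians and dashed lines mark 2-fold. Neutrophil genes reach from Ngp at -3.56 to Csf3r at 0.53, and all 11 glucocorticoid-responsive genes lie below 0.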

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

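Leaving out spots with code 64 or 65 was the 1 alternative chosen after the data were seen. The normexp background correction was not run because it needs foreground and background columns, and no replicate could be left out with 1 array per genotype. Signal over background limits the dim genes, whose ratios had an SD of 0.75 in the dimmest 10% of genes against 0.38 in the highest. The neutrophil, acute phase, glucocorticoid-responsive, muscle, interferon and fibroblast lists stood apart in the same direction, relative to the median gene, under all 13 alternatives, of which 11 are distinct, since median scaling, no scaling and the authors' value table give the same values once centred. The neutrophil median lay between -1.02 and -0.99 and the interferon median between 0.51 and 0.68. Where a cause is not named, it was not tested.

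Foxf1 kept its direction throughout, at -1.45 without scaling and -1.61 in the authors' value table, both of which leave in the shift of all genes. The counts of higher and lower genes were 1104 and 2426 without scaling, 904 and 3368 in the authors' value table, 265 and 181 with a signal-to-noise of at least 10 in both, 3265 and 3144 with no detection filter, 3202 and 2879 at 1.5-fold, 734 and 534 at 3-fold, and 617 and 402 without genes detected in 1 pool. The last 5 pairs follow from the number of genes or the threshold admitted.

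List medians, relative to the median gene, changed sides of the 2.5% limits as follows. The mast cell list lost its place with a signal-to-noise of 10 (-0.24), no detection filter (-0.019) and members detected in at least 1 pool (-0.14). The Foxf1-linked list lost it at a signal-to-noise of 10 (0.29), with members detected in at least 1 pool (0.29) and against unmatched random lists (0.29), its percentile moving between 97.0 and 98.4 over all settings. The reference genes lost it under median scaling, no scaling and the authors' value table (each -0.17), cyclic loess (-0.15), no detection filter (-0.16) and unmatched lists (-0.22). Lists that newly stood apart were chemokines at a signal-to-noise of 10 (0.29), cytokines with no detection filter (0.33), and B and plasma cell (0.75) and hepatocyte genes (-0.74) with members detected in at least 1 pool. Club and goblet cell genes did so under median scaling, no scaling and the authors' value table (each 0.26) and cyclic loess (0.32), and xenobiotic genes under the first 3 of these (each -0.19) and with coded spots kept (-0.15).

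Of 72 other named genes with a difference or bound of at least 2-fold, 1 changed sign. Cflar stood at -0.49 once spots with code 64 or 65 were left out, since its other probe was then used. Of 86 named genes under 2-fold, 42 changed sign under at least 1 alternative, 25 of them without scaling, 35 in the authors' value table and 11 under other settings, so their signs hold only relative to the median gene and some not even then. Of 1570 values of all 158 genes under the alternatives, 224 moved by more than the probe-to-probe SD, most of them without scaling or in the authors' value table.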

Other observations

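The tests of less residual blood, a uniform loss of neutrophils, the time of day, stomach tissue, antigen-presenting cells and the MHC haplotype were chosen after the results were seen, and so were all gene lists and genes named here. The test on genes beside Foxf1 was set before its result was seen.

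Genes of pulmonary neuroendocrine cells, sparse airway cells that secrete neuropeptides, were lower in the Foxf1+/- pool. All 7 members detected in both pools lay below 0, with a median log2 ratio of -0.60 (percentile 0.42). Grp (-3.54) and Calca, calcitonin gene-related peptide (-2.002), prompted the list, and the other 5, among them Uchl1 (-0.60) and Resp18 (-0.76), had a median of -0.60 (percentile 1.77). Neuronal growth genes were unequal, with Gap43 at 1.95, Stmn2 at 1.73, Tubb3 at -0.39 and Uchl1 at -0.60 (median 0.67). Semaphorins and their receptors had a median of 0.30 over 15 members (percentile 98.8). Without Sema3c and Nrp1 (1.32), which prompted the list, it was 0.29 (percentile 97.6). Of the 15 members 11 lay above 0, and those below included Sema6b (-0.91), Sema3e (-0.70) and Sema7a (-0.50). Sema3f was detected in the wild-type pool only and was at least 2.28-fold lower in the Foxf1+/- pool. Interferon-inducible GTPases of the IRG and GBP families had a median of 0.71 over 8 members, all above 0, led by Iigp1 (1.78), and of 0.68 over 7 (percentile 99.88) without Iigp1, which prompted the list together with Gbp7. The latter was detected in the Foxf1+/- pool only (at least 8.01-fold higher, and 6.90-fold without scaling), and 5 of the 8 also stand in the interferon list. Of other genes induced through the aryl hydrocarbon receptor, which induces Cyp1a1, Nqo1 was at -0.27 and Aldh3a1 at -0.06. Cyp1a2, Cyp1b1 and Ahrr were detected in neither pool, and the 3 measured members including Cyp1a1 (median -0.06) are too few to describe the list.

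Neutrophil, acute phase and glucocorticoid-responsive genes were lower together in the Foxf1+/- pool. Less residual blood is argued against by red cell transcripts, whose median was 0.426 over 3 genes (from -0.17 for Hba-a1, which carried code 4 in wild type, to 1.09 for Ahsp), against -0.999 for the neutrophil list. A uniform loss of neutrophils as the whole cause would give transcripts listed as neutrophil-restricted 1 ratio, if only neutrophils made them, and each equally. Those above the median signal had an SD of 1.525 over 6 genes, where the SD of a single probe is 0.39. Ngp (-3.56), Mmp8 (-2.06), Cxcr2 (-1.07) and Retnlg (-0.998) were lower, and Prtn3 (0.31) and Csf3r (0.53) higher. This argues against 1 ratio shared by these genes. Whether all 6 are made by neutrophils alone, or alike at each stage of maturation, was not tested. The SD of a single probe compares probes of 1 gene and leaves out such differences between genes. A loss of neutrophils is therefore not excluded. A different time of day at dissection stays open and undecided: the medians of 8 evening-phase and 4 morning-phase clock transcripts differed by 1.396, but this rests on genes whose values had prompted the question, without which 5 evening-phase genes had a median of 0.06 and 1 morning-phase gene, Clock, stood at 0.34, and with 1 pool per genotype the hour and the genotype cannot be told apart. A biological effect of Foxf1 dose on neutrophil recruitment or on glucocorticoid signalling also stays open, untested.

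Tff1, Gkn2 and Gkn1 (at least 16.1-fold higher, and 13.0-fold without scaling), genes of the gastric surface epithelium, were detected in the Foxf1+/- pool only. Carry-over of stomach tissue with all its cell types would bring the other abundant stomach transcripts. The list does not separate genes of the surface epithelium from those of other stomach cells, so it cannot decide on carry-over of surface epithelium alone. Of 15 on the array, 3 (Pga5, by a spot with code 64, Psca and Anxa10) were detected in the Foxf1+/- pool with a log2 value of at least 1. Tff2 was 1.88-fold higher (0.91), while Ctse (-0.98), Ghrl (-0.57) and Chia1 (-0.16) were lower. Pgc was detected in the wild-type pool only, and Atp4a, Atp4b, Cblif and Muc6 in neither pool. The 5 genes detected in both pools had a median of -0.16 (percentile 25.1). Of the 15 genes, 6 were detected in the wild-type pool too, and whether lung cells made them there was not tested. Carry-over of gastric surface epithelium stays open. Expression by airway epithelium of 1 or more of the mice, through genotype or otherwise, also stays open and was not tested.

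H2-Ea had a signal of 115 in the wild-type and 6902 in the Foxf1+/- pool. More antigen-presenting cells as the cause are argued against by a list of other class II genes. Its median was 0.381 over 6 members (-0.17 to 0.98, 5 above 0, percentile 97.92), far below the bound of 5.91 for H2-Ea. H2-DMb2, a class II gene outside that list, was at 0.179. A small rise in such cells is not excluded. A candidate explanation is another MHC haplotype among the outbred mice, since some mouse haplotypes do not express H2-Ea. Genes of the H2 complex had a median absolute log2 ratio of 0.715 over 16 genes against 0.29 in random lists (percentile 99.99), with H2-M3 at -1.32 and H2-Q5 at -1.14. H2-D1 (1.38), seen beforehand, carried code 64 in the Foxf1+/- array, and without it the median was 0.59 over 15 genes (percentile 99.4). The size of these ratios alone cannot tell a haplotype from another cause of differences among H2 genes. Haplotype and genotype cannot be told apart in 1 pool each. The 1 probe of H2-Ea carried software code 1 in the wild-type array, and a failed spot there was not tested.

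Strain-derived DNA kept beside the disrupted allele was tested as a source of differences. The 100 measured genes nearest to Foxf1 in reference order had a median absolute log2 ratio of 0.232, at percentile 3.06 of random matched lists. This argues against larger differences across these genes as a whole. Agt (-1.89), Gcsh (-1.39), Kcnk1 (-1.28), 6430548M08Rik (-1.01) and Wfdc1 (1.002) were at least 2-fold apart. A median cannot register changes in a few genes, so strain-derived DNA is not excluded as their source.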
